A study of Mus musculus with 3 samples.

How the data were processed

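Cells of the aortic adventitia, the outer layer of the vessel wall, were profiled by droplet-based single-cell RNA sequencing in mice given saline (Vehicle), angiotensin II (AngII) or angiotensin II with voluntary wheel running (AngII_VWR). Per the labels the series held 9 mice, 3 in each group, and each group was deposited as 1 library, and the labels did not state how the mice were combined. Per the labels the adventitia was peeled off, minced and digested with Liberase and elastase for 20 min in a bath and 40 min on a rotator. The cells then went through a 40 µm strainer and red blood cell lysis, and 3′ libraries on the 10x platform were aimed at 10000 cells each. The deposited matrices held raw counts of UMIs, molecules counted once each, per gene and barcode. Per the file headers these counts were written by Cell Ranger 7.0.1 for Vehicle and AngII and by version 7.1.0 for AngII_VWR, so the version differed with the group. The genome build was mm10 per the processing notes in the labels, and the labels did not state whether intronic reads were counted. The lowest total per barcode in the files was 500, 501 and 500 UMIs in Vehicle, AngII and AngII_VWR.

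Barcodes with at least 300 genes, at least 500 UMIs and at most 10% mitochondrial UMIs were kept, which left 13861, 9899 and 19019. Scrublet, as implemented in scanpy 1.11.5, scored doublets in each library, and the highest scores were removed at 0.8% per 1000 cells of that library. This removed 1537 barcodes (11.1%) in Vehicle, 784 (7.92%) in AngII and 2894 (15.2%) in AngII_VWR. Scrublet's own threshold would have called 292, 160 and 1. Counts were scaled to 10000 per cell and logged, and 2000 variable genes were chosen without mitochondrial and ribosomal genes. They gave 30 components, a graph of 15 neighbours and 28 Leiden clusters at resolution 0.8 (leidenalg 0.10.2), with all libraries together and no batch correction. Calculations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and scikit-learn 1.9.0.

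Clusters were named from markers of 22 cell classes, and a name such as fibroblast-like means no more than that the cluster carried those markers. The class with the highest mean marker score was taken where the score was at least 2 (log2) and at least 3 markers were at least 2-fold higher than at the 25th percentile of clusters. A cluster stayed unnamed when its 10 top genes held more markers of another class, or when its UMIs were low and none of its top genes was a marker of the class. It also stayed unnamed when the class with the next score came close. These naming rules were set after the clusters had been seen, and which lists to lead with was decided after their values had been seen. The markers, the filters, the 36 gene lists, the rule for named genes and most alternatives were chosen before the data were examined.

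UMIs were summed over the cells of a class in each library and scaled to 1000000 UMIs of the class (CPM). Ratios were log2 ratios of CPM + 1. No statistical test was possible with 1 library per group, since cells of a library are not replicates of the treatment. Both values are therefore given with 95% intervals: exact Clopper-Pearson for shares, exact Poisson for CPM and exact conditional intervals for ratios. For the median of a gene list, 1000 Poisson resamplings of the counts gave the interval. All of these intervals cover counting error alone, not differences between mice or between preparations. A list member counted as measured with a CPM of at least 5 in either library of the pair and at least 10 UMIs over both. Each list's median was placed among 10000 random lists of the same size, drawn from genes of like expression in 20 bins. The percentile describes these libraries and treats genes as independent, which they are not. Simulated libraries with 200 altered genes tested the calculations: the ratio intervals held the true value for 95.2, 94.9, 95.2 and 95.5% of genes in the 4 main comparisons. The simulated counts were Poisson draws, as the intervals assume, so this checked the calculation and not how the intervals fare in these data.

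Named genes followed a fixed rule in classes with at least 100 cells in each library. They had a CPM of at least 100 and at least 50 UMIs in the higher library, and a CPM there of at least 0.5 times that of all other cells of that library, to limit free RNA. Mitochondrial, ribosomal protein, haemoglobin, immunoglobulin and unnamed predicted genes were left out. The 5 highest and 5 lowest ratios were named in the fibroblast-like class and the 4 highest and 4 lowest in the macrophage-like class. In each list described, up to 4 members with the largest ratio and a CPM of at least 50 were named, and receptors of angiotensin and adrenaline were also examined. The smooth muscle-like and endothelial-like classes did not reach 100 cells in each library, so no genes were named there. The T-like class did, with 172, 101 and 153 cells, but the rule set no number of genes for it and none were named. Positions came from GENCODE M21 for GRCm38 (mm10). Of 32285 gene identifiers in the files, 32235 were found there by identifier.

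The alternatives changed 1 choice at a time, except that the stricter filter raised the minimum of genes and that of UMIs together, and that equal cluster weights also left out the clusters with under 100 cells in a library. They were at most 5% or 20% mitochondrial UMIs, at least 1000 genes and 2000 UMIs per cell, no doublet removal, Leiden resolution 1.6, and classes from a marker score per cell. Further ones were shares among cells outside the fibroblast-like class, scaling by the median ratio of genes, equal weight per cell, cells thinned to 1500 UMIs, a pseudocount of 5 CPM, and 5% free RNA subtracted. The lists were also run with all members of at least 1 UMI and with a CPM of at least 20, and the named genes without the free RNA rule and with a CPM of at least 300. Added after seeing the data were naming every cluster by its highest score, leaving out clusters 9 and 11, equal weights for the clusters with at least 100 cells in each library (fibroblast-like 2, 6, 8 and 10, macrophage-like 1 and 7), leaving out cluster 20, and giving list medians, counts of list members and opposite genes relative to the median of all genes. No replicate could be left out and no other split of the samples could be made with 1 library per group. No paired analysis was possible because no sample of one group was matched to a sample of another.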

Results

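Single-cell RNA profiles were collected from the aortic adventitia of mice given saline (Vehicle), angiotensin II (AngII), a hormone that raises blood pressure, or angiotensin II with access to a running wheel (AngII_VWR). The labels gave 3 mice per group and did not state how they were combined, and each group was deposited as 1 library, so there were no replicates. The files held 15093, 10515 and 19633 barcodes with 165977330, 141570158 and 105679209 UMIs in Vehicle, AngII and AngII_VWR. After filtering, 12324, 9115 and 16125 cells remained, 37564 in all, with a median of 9408.5, 13129 and 4474 UMIs and 3000.0, 3661 and 2017 genes per cell. Fibroblast-like cells, named from marker genes, had a median of 17533, 15493 and 5533 UMIs, and macrophage-like cells 13327, 15090.0 and 4839. The median mitochondrial share was 1.72, 2.49 and 2.34%. Haemoglobin took 2.68% of all UMIs in Vehicle, 0.472% in AngII and 0.139% in AngII_VWR. The Y-linked Ddx3y gave 15732, 15923 and 10879 UMIs, and Xist gave 18, 13 and 7.

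Fibroblast-like and macrophage-like cells were the largest named classes in every library. Fibroblast-like cells made up 20.5% of Vehicle cells (19.8 to 21.2%), 43.0% of AngII cells (42.0 to 44.1%) and 50.2% of AngII_VWR cells (49.4 to 51.0%). Macrophage-like cells made up 18.2, 20.8 and 20.2%. Neutrophil-like cells made up 0.0325% in Vehicle, 0.219% in AngII and 1.80% in AngII_VWR, from 4, 20 and 291 cells. Their share was 8.22 times higher in AngII_VWR than in AngII (5.23 to 13.7). Smooth muscle-like cells, which belong to the layer under the adventitia, made up 4.65% in Vehicle, 0.187% in AngII and 0.254% in AngII_VWR. T-like cells made up 1.40, 1.11 and 0.949%, and Schwann-like cells, the glia of peripheral nerves, 0.260, 0.230 and 0.310%.

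Unnamed clusters held 51.5% of Vehicle, 30.6% of AngII and 24.0% of AngII_VWR cells, and the fibroblast-like share rested on them. Clusters 0, 3 and 4, the largest of these, scored highest on fibroblast markers but carried top genes of other types or low UMIs. Naming every cluster by its highest score gave 8318, 6402 and 11478 fibroblast-like cells, and the ratio of AngII over Vehicle shares went from 2.10 (2.00 to 2.21) to 1.04. It was 1.23 with at least 1000 genes and 2000 UMIs per cell and 1.35 with a marker score per cell, which turned AngII_VWR over AngII from 1.17 to 0.933. The macrophage-like share, 1.14 times higher in AngII than in Vehicle, turned to 0.628 with up to 20% mitochondrial UMIs, 0.572 with the stricter filter and 0.763 at Leiden resolution 1.6. In AngII_VWR over AngII, 0.971 became 1.599, 1.34 and 1.31 under the same settings, and 1.11 among cells outside the fibroblast-like class. The neutrophil-like ratio was 2.62 with the stricter filter, and the smooth muscle-like ratio of AngII over Vehicle went from 0.0401 to 0.184 with a score per cell.

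**Figure D1:**
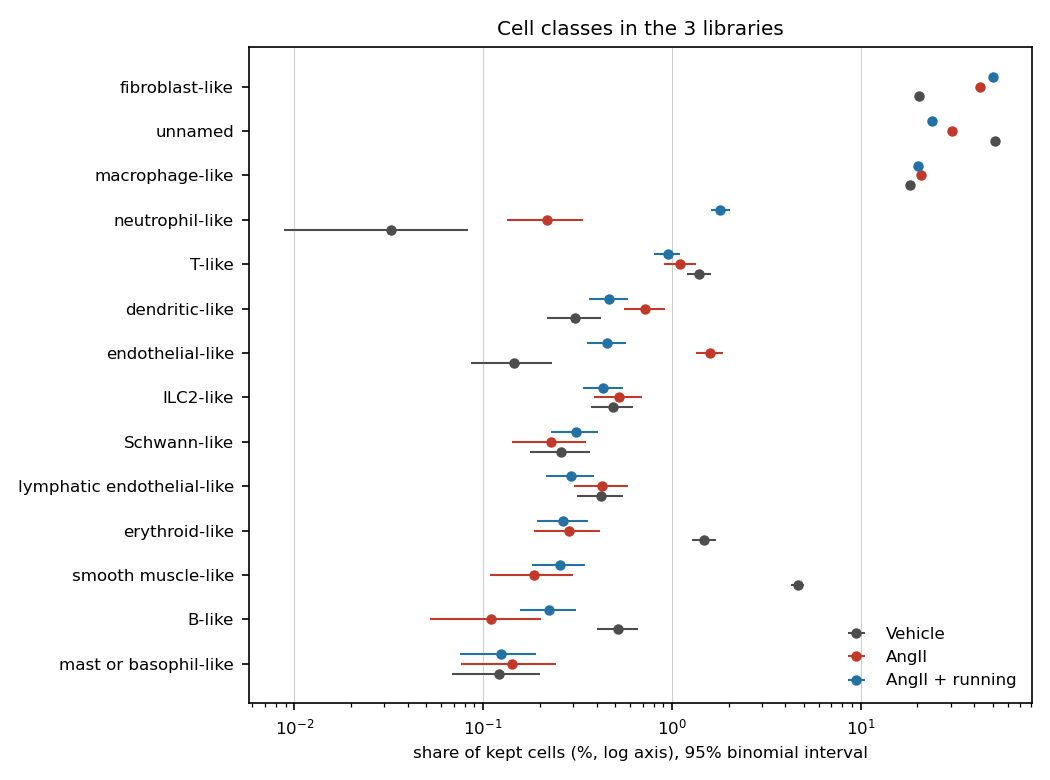
Share of kept cells in each class (percent, log axis) in the 3 libraries, with 1 point per library and bars for exact 95% binomial intervals. Fibroblast-like cells lie at 20.5% in Vehicle, 43.0% in AngII and 50.2% in AngII_VWR, and neutrophil-like cells at 0.0325, 0.219 and 1.80%.

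The first comparison, AngII against Vehicle, addresses how adventitial cells differ under the hormone. In fibroblast-like cells, genes of myofibroblasts, which are activated matrix-producing fibroblasts, were higher in AngII, and genes of adventitial progenitor fibroblasts were lower. The myofibroblast list had a median log2 ratio of 2.02 (1.90 to 2.15), with 13 of 14 measured members higher and 11 of them at least 1.5-fold higher. The progenitor list had a median of −1.57 (−1.59 to −1.55), with 10 of 10 members at least 1.5-fold lower. Collagen and matricellular genes were also higher, with a median of 0.78 (0.77 to 0.80) and 19 of 23 members higher. Genes of the unfolded protein response, which handles misfolded protein in the endoplasmic reticulum, were lower in 14 of 14 cases, with a median of −0.76 (−0.78 to −0.72).

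Among myofibroblast genes, Comp, which encodes a cartilage matrix protein, stood at 1399 CPM in AngII and 125 CPM in Vehicle, and Cthrc1 at 246 and 22.3 CPM. Tenascin C (Tnc) stood at 95.3 CPM in AngII and 1.75 CPM in Vehicle. In the collagen and matricellular list, Col8a1 stood at 711 CPM against 69.4 CPM and periostin (Postn) at 514 CPM against 67.0 CPM. The elastic fibre list was split, with 10 of 16 members higher and a median of 0.36. Ltbp2 was higher in AngII, at 154 against 30.1 CPM, and the fibrillin gene Fbn1 was lower, at 875 against 2117 CPM. Of the matrix proteases and their inhibitors, 10 of 15 were higher (median 0.30), with Adamts4 at 67.3 against 5.61 CPM, Mmp2 at 600.4 against 228 CPM, and Adamts5 lower at 232 against 727 CPM. Progenitor genes included Dpp4, at 27.3 CPM in AngII and 124 CPM in Vehicle, and Sema3c, at 169 and 702 CPM. Cytokine and chemokine genes were higher in 11 of 16 cases (median 0.49). Interleukin 6 (Il6) stood at 615 CPM in AngII and 109 CPM in Vehicle, Ptgs2, the inducible cyclooxygenase, at 529 and 244 CPM, and the eosinophil attractant Ccl11 at 75.9 and 266 CPM. In the unfolded protein response, the chaperone Hspa5 stood at 834 CPM in AngII and 1917 CPM in Vehicle, and Sdf2l1 at 35.9 and 98.4 CPM.

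Of 1751 genes that met the expression rule, 120 were at least 2-fold higher and 103 at least 2-fold lower in AngII. Thbs4 (ENSMUSG00000021702, chromosome 13, 92751590 to 92794818), which encodes a matricellular thrombospondin, had the highest ratio, 132 CPM (129 to 135) against 1.82 CPM (1.44 to 2.26), or 72.6-fold (58.4 to 91.5). Kcnma1, the pore-forming subunit of a calcium-activated potassium channel, followed at 32.5-fold (29.8 to 35.5). Rrad, a small GTPase, was 20.6-fold higher, Ndnf 16.4-fold and Ecrg4 15.01-fold. Lower genes were Smpd3, a sphingomyelinase, at 5.86-fold lower, Dact2 at 5.16-fold, Car8 at 4.92-fold and Limch1 at 4.73-fold. Cd55 (ENSMUSG00000026399, chromosome 1, 130439027 to 130462744), which encodes an inhibitor of complement, was 4.60-fold lower (4.51 to 4.69), at 193 CPM in AngII and 887 CPM in Vehicle.

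The fibroblast-like class lay mainly in clusters 10, 2 and 6 in Vehicle (36.5, 30.1 and 26.7% of the class) and in clusters 9 and 2 in AngII (45.1 and 19.2%). Cluster 9 held 19 Vehicle, 1769 AngII and 57 AngII_VWR cells, so it cannot be separated from its library. Thbs4, Ecrg4, Ndnf, Kcnma1, Col8a1, Tnc and Il6 were top genes of cluster 9. Cd55, Dact2, Limch1, Car8, Dpp4 and Sema3c were top genes of cluster 10, which held 6.83% of the AngII class. The clusters had been built partly from these genes. The progenitor median was −0.37 with equal weights for shared clusters. Cd55, 4.60-fold lower, had a log2 ratio of −2.19 that became −1.31 without clusters 9 and 11 and −0.31 with those weights, and Thbs4 went from 5.56 to 3.87 and 2.61. Erythroid markers summed to 778 CPM in the Vehicle class and 145 CPM in AngII, and macrophage markers to 107 and 113 CPM. Without clusters 9 and 11 the myofibroblast median was 1.32, the collagen median 0.52, and 47 and 30 genes were at least 2-fold higher and lower, and with equal weights for shared clusters the myofibroblast and collagen medians were 0.70 and 0.30. A score per cell gave 77 and 46 genes, or 79 and 49 with every cluster named. The myofibroblast median was 3.06 with free RNA subtracted. Smooth muscle markers, some of them in this list, summed to 138 CPM in the Vehicle class and 5811 CPM in the other Vehicle cells. In AngII these sums were 203 and 274 CPM. Subtracting 5% thus removed more of these markers in Vehicle than the class held, so 3.06 cannot be read as a larger difference.

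In macrophage-like cells, the genes of MHC class II, which present antigen to T cells, were higher in AngII than in Vehicle, and genes of resident macrophages were lower. The MHC class II list had a median log2 ratio of 1.56 (1.50005 to 1.64), with 8 of 8 measured members higher and 7 of them at least 1.5-fold higher. Genes of classical activation were higher in 11 of 12 cases, with a median of 0.71 (0.62 to 0.75). The resident or alternative list had a median of −0.53 (−0.54 to −0.52), with 14 of 17 members lower. Cytokine and chemokine genes were higher in 12 of 21 cases, with a median of 0.58 (0.55 to 0.62). Each of these medians lay above or below all 10000 random lists. In fibroblast-like cells the MHC class II list had a median of 1.65 in AngII over Vehicle, with 5 of 5 measured members at least 1.5-fold higher. The class II gene Cd74 stood there at only 79.1 CPM in AngII and 27.9 CPM in Vehicle. Free RNA from other cells was not excluded as the source.

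The class II genes H2-Ab1 and H2-Aa stood at 4615 and 5195 CPM in AngII and 1294 and 1483 CPM in Vehicle, and their transactivator Ciita at 56.2 and 17.7 CPM. Among activation genes, Ccr2 (ENSMUSG00000049103, chromosome 9, 124101950 to 124113557), the chemokine receptor that marks recruited monocytes, stood at 160.3 CPM in AngII (156 to 165) and 6.998 CPM in Vehicle (6.09 to 7.999), or 22.9-fold (20.0 to 26.4). Interleukin 1 beta (Il1b) stood at 1832 and 304 CPM, 6.03-fold higher (5.90 to 6.17), and Cd80 at 194 and 77.5 CPM. The chemokine genes Ccl8 and Cxcl13 stood at 1670.0 and 64.5 CPM in AngII and 328 and 2.67 CPM in Vehicle. The resident marker Timd4 was 3.47-fold lower, ficolin A (Fcna) 3.43-fold, Retnla 3.15-fold, and Lyve1 stood at 476 CPM against 1285 CPM. Other named genes were Tnip3, an inhibitor of NF-kB signalling, 11.3-fold higher, Abtb2, 6.55-fold higher, and the heat shock gene Hspa1b, 3.19-fold lower.

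Of 1701 genes that met the rule in this class, 57 were at least 2-fold higher and 36 lower in AngII. Genes of dissociation stress, early response and heat shock genes that tissue digestion induces, were lower in 23 of 24 cases (median −0.83). In the fibroblast-like class the same list had a median of −0.08. The unfolded protein response list was lower in 13 of 13 cases (median −0.50). Smooth muscle markers in the macrophage-like class summed to 126 CPM in Vehicle and 8.10 CPM in AngII, erythroid markers to 814 and 59.8 CPM, and dendritic markers to 120.1 and 53.2 CPM. Monocyte markers, among them Ccr2, summed to 35.6 CPM in Vehicle, 217 CPM in AngII and 189 CPM in AngII_VWR. The class lay mainly in cluster 1 in Vehicle (88.0%) and in clusters 7 and 1 in AngII (56.3 and 41.8%). With up to 20% mitochondrial UMIs, the stricter filter and Leiden resolution 1.6, the AngII class held 1044, 1032 and 1095 cells instead of 1900, the class II median was 0.66, 0.66 and 0.91, the resident median −0.21, −0.23 and −0.044, and 12, 13 and 19 genes were 2-fold higher and 11, 9 and 14 lower. Equal weights for shared clusters gave 0.34 for class II and −0.10 for the resident list, and the clusters had been built partly from these genes.

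**Figure D2:**
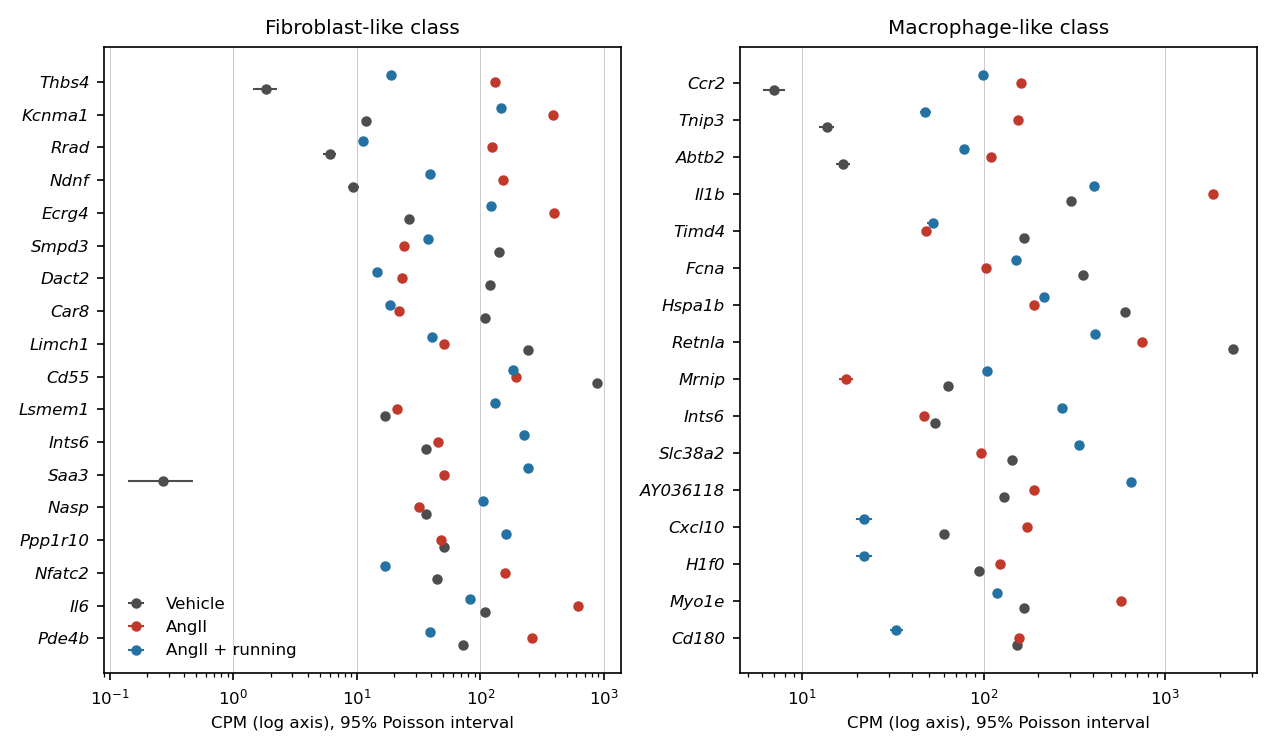
Expression of the named genes (CPM, log axis) in the fibroblast-like and macrophage-like classes, with 1 point per library and bars for exact 95% Poisson intervals. Thbs4 lies at 1.82 CPM in Vehicle, 132 CPM in AngII and 18.9 CPM in AngII_VWR, and Il1b at 304, 1832 and 406 CPM.

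The second comparison, AngII_VWR against AngII, addresses what differs with habitual exercise under the hormone. In fibroblast-like cells the median ratio of all measured genes was 0.13 log2, so list medians and counts of members are given relative to it, a choice made after seeing the data. Myofibroblast genes were lower in AngII_VWR, at −0.87 relative to all genes, with 13 of 14 members lower, and collagen and matricellular genes at −0.41, with 20 of 23 lower. Cytokine and chemokine genes were lower in 13 of 18 cases, at −0.30. Unfolded protein response genes were higher in 12 of 13 cases, at 0.41. Progenitor genes lay at −0.08, or at −0.82 without clusters 9 and 11, and stayed under their Vehicle levels.

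Comp stood at 629 CPM in AngII_VWR and 1399 CPM in AngII, Cthrc1 at 105 and 246 CPM, Postn at 286 and 514 CPM, and Sparc, a collagen-binding protein, at 6356 and 11086 CPM. Of the elastic fibre genes 9 of 16 were lower (−0.27), and Mfap4 stood at 564 against 1616 CPM. Of the TGF-beta response genes 9 of 15 were lower (−0.38), while in AngII over Vehicle 8 of 15 were lower, with a median of −0.03. Among cytokine genes, Il6 (ENSMUSG00000025746, chromosome 5, 30013114 to 30019981) was 7.49-fold lower (7.25 to 7.73), at 82.2 CPM in AngII_VWR (79.7 to 84.7) and 615 CPM in AngII (609 to 621). The neutrophil attractant Cxcl1 stood at 249 and 1117 CPM, and Ccl7 at 157 and 474 CPM. The stromelysin gene Mmp3 was higher, at 1371 against 465 CPM, in a protease list with a median of −0.16. In the unfolded protein response, Sdf2l1 stood at 118 CPM in AngII_VWR and 35.9 CPM in AngII, and Manf at 509.8 and 236 CPM. Genes of the type I interferon response were lower in 13 of 14 cases (−0.69). They were also lower in AngII than in Vehicle, in 12 of 15 cases (median −0.39). Cluster 16, with the interferon genes Ifit3 and Isg15 among its top genes, was left unnamed and lay outside both classes. It held 173 Vehicle, 83 AngII and 76 AngII_VWR cells.

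Of 1704 genes that met the rule, 24 were at least 2-fold higher and 51 lower in AngII_VWR. Rrad was 11.03-fold lower, the transcription factor Nfatc2 9.35-fold, Thbs4 6.97-fold and the cAMP phosphodiesterase Pde4b 6.71-fold. Lsmem1 was 6.28-fold higher, Ints6, a subunit of the Integrator complex, 4.97-fold, the histone chaperone gene Nasp 3.34-fold and Ppp1r10 3.30-fold. The acute-phase gene Saa3 (ENSMUSG00000040026, chromosome 7, 46711998 to 46715700) stood at 241 CPM in AngII_VWR (237 to 245), 51.1 CPM in AngII (49.3 to 52.8) and 0.269 CPM in Vehicle (0.139 to 0.470). Cluster 20, with Saa3 and Mmp3 among its top genes, held 1 Vehicle, 17 AngII and 194 AngII_VWR cells. Without it Saa3 stood at 6.81 CPM in AngII_VWR and 4.87 CPM in AngII, and Mmp3 at 1080.4 and 452 CPM. Of the 24 higher genes, 20 had at least 50 CPM in macrophage-like cells, and 18 of these were at least 1.5-fold higher there too. Ints6, Nasp and Ppp1r10 were among these 18, so a difference of the whole library was not separated from one of this class. Of the 51 lower genes, 25 had at least 50 CPM in macrophage-like cells, and 8 of these were at least 1.5-fold lower. Macrophage markers in the fibroblast-like class summed to 346 CPM in AngII_VWR and 113 CPM in AngII, and the resident macrophage list was higher there in 10 of 12 cases (1.24 relative to all genes). The dissociation stress list had a median of −0.44. The AngII_VWR class lay mainly in clusters 5, 2, 8 and 6 (28.2, 24.9, 22.9 and 18.3%), and the AngII class in clusters 9 and 2. Thbs4 and Il6 were among the top genes of cluster 9. Without clusters 9 and 11 the myofibroblast median relative to all genes went from −0.87 to −0.21, the collagen median from −0.41 to −0.22, and 17 genes were 2-fold lower. With equal weights for shared clusters both lists kept their sign, at −0.28 and −0.25.

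In macrophage-like cells the median of all measured genes was 0.19 log2 in AngII_VWR over AngII. Relative to it, MHC class II genes were lower at −1.52, with 8 of 8 members at least 1.5-fold lower. Classical activation genes were lower at −0.97 in 11 of 12 cases, cytokine and chemokine genes at −0.98 in 18 of 22 cases, and interferon genes at −0.96 in 15 of 15 cases. The interferon value leaves out the unnamed cluster 16, which scored highest on macrophage markers. Unfolded protein response genes were higher in 12 of 13 cases, at 0.46. The resident or alternative list was split, with 6 of 18 members higher and a median of −0.24.

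H2-Ab1 stood at 1492 CPM in AngII_VWR and 4615 CPM in AngII, Cd74, the class II invariant chain, at 4627 and 13767 CPM, and Ciita at 20.0 and 56.2 CPM. Il1b stood at 406 and 1832 CPM and Cd80 at 71.9 and 194 CPM. Cxcl10 (ENSMUSG00000034855, chromosome 5, 92346638 to 92348889), an interferon-induced chemokine, was 7.92-fold lower (7.14 to 8.81), at 21.9 CPM (19.8 to 24.2) against 174 CPM (169 to 178). Other lower genes were the linker histone H1f0, 5.63-fold, Myo1e, 4.85-fold, and Cd180, 4.74-fold. Among resident genes Lyve1 was higher, at 1063 CPM against 476 CPM, and Retnla lower, at 411 CPM against 749 CPM. Mrnip was 5.97-fold higher, Ints6 5.73-fold, the amino acid transporter Slc38a2 3.46-fold and the long noncoding AY036118 3.41-fold. In the unfolded protein response, Dnajb9 stood at 174 and 75.9 CPM and Atf4 at 184 and 86.9 CPM.

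Of 1803 genes that met the rule, 28 were at least 2-fold higher and 57 lower in AngII_VWR. Of the 28 higher genes, 25 had at least 50 CPM in fibroblast-like cells and 21 were at least 1.5-fold higher there. Ints6, Slc38a2 and AY036118 were among these 21, so a difference of the whole library was not separated from one of this class. Of the 57 lower genes, 18 had at least 50 CPM in fibroblast-like cells and 8 were at least 1.5-fold lower. Fibroblast markers in the macrophage-like class summed to 2210 CPM in AngII_VWR, 749 CPM in AngII and 847 CPM in Vehicle, and 21 of 21 measured collagen and matricellular genes were higher in AngII_VWR there (1.03 relative to all genes). The AngII_VWR class lay mainly in clusters 7, 11 and 1 (39.2, 36.9 and 23.9%), and cluster 11 held 140 Vehicle, 36 AngII and 1203 AngII_VWR cells. The class II median relative to all genes, −1.52, was −0.98, −0.99 and −1.05 with up to 20% mitochondrial UMIs, the stricter filter and every cluster named. Scaling by the median ratio gave 14 genes at least 2-fold higher instead of 28.

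**Figure D3:**
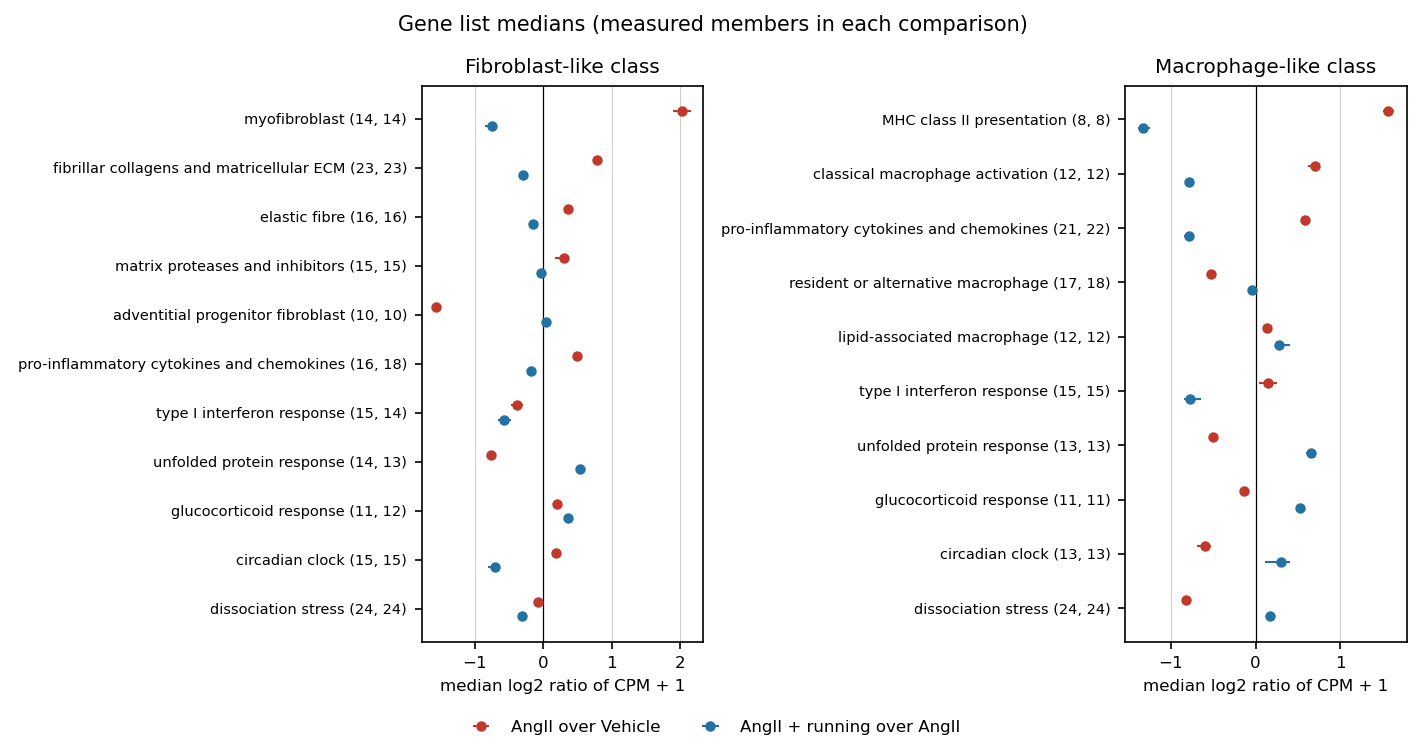
Median log2 ratio of CPM + 1 of gene lists in the fibroblast-like and macrophage-like classes for AngII over Vehicle and AngII_VWR over AngII, with the measured members of each comparison in brackets and bars for 95% intervals from Poisson resampling. Myofibroblast genes lie at 2.02 and −0.74 and MHC class II genes at 1.56 and −1.33, before the shift of all genes is taken off.

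The comparison of AngII_VWR with Vehicle shares a library with each of the others. The alternatives were not run for this comparison. Myofibroblast genes stayed higher than in Vehicle (median 1.34 log2, 11 of 13 members higher), as did collagen and matricellular genes (0.51, 17 of 23), and progenitor genes stayed lower (−1.55, 10 of 10). Cluster 10, with the progenitor genes Dpp4 and Sema3c among its top genes, held 36.5% of the fibroblast-like class in Vehicle and 2.57% in AngII_VWR. In macrophage-like cells, where the median of all genes was 0.17, MHC class II genes lay at −0.09 relative to all genes, with 3 of 8 members higher. Resident genes lay at −0.84, with 15 of 18 lower.

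Genes with a 2-fold difference between AngII and Vehicle were followed into AngII_VWR, where a gene counted as lying back when its AngII_VWR over AngII ratio pointed toward Vehicle relative to the median of all genes. This correction was added after seeing the data. In fibroblast-like cells 108 of the 120 higher genes lay back (90.0%), against 58.6% of 1301 genes less than 1.5-fold apart between AngII and Vehicle. Of the 103 lower genes 60 lay back (58.3%), against 41.4% of those other genes. In macrophage-like cells 56 of the 57 higher genes lay back (98.2%), against 68.7% of 1425 other genes, and 17 of the 36 lower genes (47.2%), against 31.3%. Without the correction the counts were 96, 76, 55 and 24, and the lower genes had median ratios of 0.19 and 0.18, near the 0.13 and 0.19 of all genes, so those counts carried the shift of the library. In AngII_VWR 63 of the higher and 72 of the lower genes of fibroblast-like cells were still 2-fold from Vehicle, as were 16 and 18 in macrophage-like cells. The AngII library enters both comparisons, which by itself places genes opposite. With the AngII cells split at random so that each comparison used separate cells, 108 of 120 higher and 57 of 102 lower genes of fibroblast-like cells, and 52 of 52 and 19 of 35 of macrophage-like cells, lay back relative to all genes, but the split removes the sampling of cells alone and not what the library shares.

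Angiotensin and adrenergic receptors and nerve-related genes were examined because the study concerned interaction of nerves and immune cells. In fibroblast-like cells the angiotensin receptor Agtr1a (ENSMUSG00000049115, chromosome 13, 30336441 to 30382867) stood at 8.48 CPM in Vehicle (7.65 to 9.38), 4.62 CPM in AngII (4.11 to 5.18) and 3.89 CPM in AngII_VWR (3.37 to 4.47). Agtr1b stood at 0.292 CPM in Vehicle, 3.24 CPM in AngII and 4.33 CPM in AngII_VWR. The adrenergic receptor Adra1b stood at 20.1 CPM in Vehicle, 4.50 CPM in AngII and 4.43 CPM in AngII_VWR. In macrophage-like cells Adrb1 stood at 6.31, 5.10 and 5.39 CPM in the same order. Adra1d gave no UMI in macrophage-like cells, which allows up to 0.120, 0.125 and 0.212 CPM. Agtr1a stood at 0.0651, 0.102 and 0.287 CPM there (at most 0.669) and Agtr1b at 0.0976, 0.102 and 0.115 CPM (at most 0.414). Neurotrophin and axon guidance genes in fibroblast-like cells had a median of −0.39 in AngII over Vehicle, with 12 of 19 lower. The repulsive guidance genes Sema3c and Sema3e stood at 169 and 18.1 CPM against 702 and 68.6 CPM, and Slit2 and Ntf3 at 196 and 52.7 CPM against 66.4 and 18.0 CPM. In AngII_VWR over AngII 9 of 19 were higher than the median of all genes, at −0.04 relative to it. Slit3 stood at 704 and 363 CPM, and Ntn1 at 235 and 111 CPM.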

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

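Some tests were chosen only after the results were seen. They were those with every cluster named by its highest score, without clusters 9 and 11, without cluster 20, and with shared clusters weighted equally. Taking list medians, counts of list members and opposite genes relative to all genes was also chosen then. The rest were planned. Of 194 alternative values of 26 share ratios, 28 lay on the other side of 1. For the 11 ratios of at least 1.5-fold, 82 of 84 values kept their direction and 2, both of B-like cells, turned. Of 2266 alternative values of 138 list medians, 132 had the other sign. For the 30 medians of at least 1.5-fold, 483 of 489 values kept their direction, 1 turned and 5 came to 0 after free RNA was subtracted. All 524 values of the 36 named genes kept their direction, although 333 lay outside the counting interval of the first value. These genes had been picked for the largest ratios in the same libraries, so a change of direction was unlikely from the start. Where values moved, the cause was not tested. List medians in this part are given before the shift of all genes is taken off. Depth limits the AngII_VWR library most, with a median of 4474 UMIs per cell against 13129 in AngII and 9408.5 in Vehicle.

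The B-like share ratio of AngII_VWR over AngII, 2.03, was 0.775 with the stricter filter and 0.747 with doublets. The fibroblast-like share ratio of AngII over Vehicle, 2.10, was 1.65 at 5% mitochondrial UMIs, 1.78 at 20%, 1.23 with the stricter filter and 1.84 with doublets, and 1.76 at resolution 1.6, 1.35 with cell scores and 1.04 with every cluster named. That of AngII_VWR over AngII, 1.17, was 1.22 at 5% mitochondrial UMIs, 1.21 at 20%, 1.04 with doublets, 1.25 at resolution 1.6, 0.933 with cell scores and 1.01 with every cluster named. The macrophage-like share ratio of AngII over Vehicle, 1.14, was 1.07 at 5% mitochondrial UMIs, 0.628 at 20%, 0.572 with the stricter filter and 1.04 with doublets, and 0.763 at resolution 1.6, 1.07 with every cluster named and 1.597 outside the fibroblast-like class. That of AngII_VWR over AngII, 0.971, was 1.599 at 20% mitochondrial UMIs, 1.34 with the stricter filter, 1.31 at resolution 1.6, 0.851 with cell scores and 1.11 outside the fibroblast-like class. The neutrophil-like ratio of AngII_VWR over AngII, 8.22, was 2.62 with the stricter filter. The smooth muscle-like ratio of AngII over Vehicle, 0.0401, was 0.184 with cell scores.

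In fibroblast-like cells the collagen median of AngII over Vehicle, 0.78, was 0.89 at 20% mitochondrial UMIs, 0.90 with the stricter filter, 0.77 at resolution 1.6, 0.82 with cell scores, 0.77 with every cluster named and 0.85 with median-ratio scaling, and 0.70 with equal cell weights, 0.69 after thinning, 0.81 after subtracting free RNA, 0.52 without clusters 9 and 11 and 0.30 with equal cluster weights. The myofibroblast median, 2.02, was 1.86 at 5% mitochondrial UMIs, 1.73 at 20%, 1.89 at resolution 1.6, 1.80 with cell scores, 1.82 with every cluster named and 1.72 with equal cell weights, and 1.52 after thinning, 1.53 with a pseudocount of 5, 3.06 after subtracting free RNA, 1.32 without clusters 9 and 11 and 0.70 with equal cluster weights. The value of 3.06 carries the over-subtraction of smooth muscle markers in Vehicle given above. The count of genes at least 2-fold higher, 120, was 77 with cell scores, 79 with every cluster named and 47 without clusters 9 and 11. The count of genes at least 2-fold lower, 103, was 46 with cell scores, 49 with every cluster named and 30 without clusters 9 and 11. For AngII_VWR over AngII the collagen median, −0.29, was −0.33 at 5% mitochondrial UMIs, −0.26 at 20%, −0.26 with every cluster named, −0.41 with median-ratio scaling and −0.25 with equal cell weights, and −0.23 after thinning, −0.16 without clusters 9 and 11, −0.16 with equal cluster weights and −0.32 without cluster 20. The myofibroblast median there, −0.74, was −0.60 with the stricter filter, −0.89 with doublets, −0.65 at resolution 1.6 and −0.87 with median-ratio scaling, and −0.66 with a pseudocount of 5, −0.14 without clusters 9 and 11, −0.18 with equal cluster weights and −0.65 with all members. The count of genes at least 2-fold lower there, 51, was 17 without clusters 9 and 11.

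In macrophage-like cells the resident median of AngII over Vehicle, −0.53, was −0.51 at 5% mitochondrial UMIs, −0.21 at 20%, −0.23 with the stricter filter, −0.51 with doublets, −0.044 at resolution 1.6 and −0.57 with every cluster named, and −0.50 with median-ratio scaling, −0.45 with equal cell weights, −0.44 after thinning, −0.54 without clusters 9 and 11, −0.10 with equal cluster weights and −0.48 with all members. The MHC class II median, 1.56, was 0.66 at 20% mitochondrial UMIs, 0.66 with the stricter filter, 0.91 at resolution 1.6, 1.49 with cell scores and 1.30 with every cluster named, and 1.44 with equal cell weights, 1.41 after thinning, 1.49 with a pseudocount of 5 and 0.34 with equal cluster weights. The count of genes at least 2-fold higher, 57, was 12 at 20% mitochondrial UMIs, 13 with the stricter filter and 19 at resolution 1.6. The count of genes at least 2-fold lower, 36, was 11 at 20% mitochondrial UMIs, 9 with the stricter filter and 14 at resolution 1.6. For AngII_VWR over AngII the resident median, −0.048, was −0.072 at 5% mitochondrial UMIs, −0.45 at 20%, −0.36 with the stricter filter, −0.20 with doublets, −0.27 at resolution 1.6 and 0.011 with cell scores, and −0.067 with every cluster named, −0.24 with median-ratio scaling, −0.026 after thinning, −0.17 without clusters 9 and 11, −0.18 with equal cluster weights and −0.069 at a CPM of 20. The MHC class II median there, −1.33, was −0.84 at 20% mitochondrial UMIs, −0.85 with the stricter filter, −1.45 with doublets, −0.95 at resolution 1.6, −1.42 with cell scores and −0.89 with every cluster named, and −1.52 with median-ratio scaling, −1.25 with a pseudocount of 5, −1.07 without clusters 9 and 11, −1.07 with equal cluster weights and −1.20 with all members. The myofibroblast list, 0.91, was −0.039 with every cluster named. The count of genes at least 2-fold higher there, 28, was 14 with median-ratio scaling.

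The percentage of fibroblast-like genes 2-fold higher in AngII that lay back toward Vehicle, 80.0, was 90.0 relative to the median of all genes. The percentage of fibroblast-like genes 2-fold lower in AngII that lay back toward Vehicle, 73.8, was 58.3 relative to the median of all genes. The percentage of macrophage-like genes 2-fold lower in AngII that lay back toward Vehicle, 66.7, was 47.2 relative to the median of all genes.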

Other observations

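All tests in this part were chosen only after the results were seen, although thinning the cells, the stricter filter and keeping doublets had been listed before.

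Complement genes of fibroblast-like cells were higher in AngII than in Vehicle in 10 of 12 cases, with a median log2 ratio of 0.16. C4b stood at 253 CPM in AngII and 79.7 CPM in Vehicle. Nox4, a NADPH oxidase that produces hydrogen peroxide, stood at 272 CPM in Vehicle, 513 CPM in AngII and 735 CPM in AngII_VWR. The mechanically gated channel gene Piezo2 stood at 26.5, 242 and 182 CPM in the same order. The adhesion genes Vcam1 and Icam1 stood at 264 and 239.8 CPM in AngII against 52.6 and 67.5 CPM in Vehicle. Relative to all genes, glycolysis genes were lower in AngII_VWR than in AngII in 14 of 16 cases, at −0.40.

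In macrophage-like cells, osteopontin (Spp1), a gene of macrophages that take up lipid, stood at 3.06 CPM in Vehicle, 69.6 CPM in AngII and 136 CPM in AngII_VWR, and Fabp5 at 6.35, 63.1 and 103 CPM. Endothelial-like cells made up 0.146% of Vehicle, 1.59% of AngII and 0.453% of AngII_VWR cells. Dendritic-like cells made up 0.308, 0.724 and 0.465%, and ILC2-like cells 0.487, 0.527 and 0.434%.

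MHC class II genes of macrophage-like cells were higher in AngII than in Vehicle and lower in AngII_VWR than in AngII. With every cell thinned to 1500 UMIs the medians, before the shift of all genes was taken off, were 1.41 and −1.32. Thinned cells kept the classes set at full depth, and thinning leaves the expected proportions within a cell unchanged. It therefore could not test depth acting through filtering, clustering or naming, and depth stays open. Dendritic cells in doublets or free RNA were argued against for AngII over Vehicle. Cells like the dendritic-like class would have to make up 36.8% of the macrophage-like UMIs. The markers they would bring, such as Clec9a (386 CPM in them, 0.510 CPM in the macrophage-like class), showed a median of 0.30% of the needed excess. For cells like the unnamed cluster 14, which carried Cd209a, the median was 0.42%. Flt3 showed the most, 4.85 and 19.9%, and stood at 0.391 CPM in Vehicle and 4.69 CPM in AngII in the macrophage-like class. With shared clusters weighted equally the medians were 0.34 and −1.07, so the first may lie largely in which clusters each library held, while the second was kept. The clusters were built partly from these genes, and the treatment itself and the single preparation per group stay open. In fibroblast-like cells the class II median was 1.65 over 5 measured members in AngII over Vehicle. In AngII_VWR over AngII it was 0.47 over 7 measured members there, before the shift of all genes was taken off. Cd74 stood at 27.9, 79.1 and 85.7 CPM in fibroblast-like cells of Vehicle, AngII and AngII_VWR. The free RNA share of that class, from macrophage markers, was 0.953% in AngII and 3.19% in AngII_VWR. Free RNA from other cells therefore stays open for both fibroblast-like medians.

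Neutrophil-like cells, short-lived phagocytes of the blood, held a larger share of AngII_VWR than of AngII cells. Barcodes with few UMIs were argued against as the whole cause, since with the stricter filter 75 and 18 cells still gave a ratio of 2.62 (1.55 to 4.67). Blood left in the tissue stays open, since of the lymphocytes that blood also carries, T-like cells had a ratio of 0.856 (0.662 to 1.11) and B-like cells 2.03 (0.989 to 4.60), which turned to 0.775 with the stricter filter and 0.747 with doublets kept. Against blood, the erythroid-like ratio was 0.935 (0.562 to 1.58) and haemoglobin was lower in AngII_VWR (0.139%) than in AngII (0.472%), although red cells had been lysed. The Cell Ranger version differed with the group and stays open, as do the running itself and a single preparation.

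Glucocorticoid response genes, which corticosterone induces, were higher relative to all genes in AngII_VWR than in AngII in 7 of 12 cases in fibroblast-like cells (median 0.23) and in 7 of 11 in macrophage-like cells (0.34), with Fkbp5 at 334 against 185 CPM in the former. These counts were near an even split, and the remaining members lay lower. Among them, Per1 and Mt1 had log2 ratios of −0.84 and −0.72 in fibroblast-like cells, and Mt1 and Errfi1 −0.46 and −0.30 in macrophage-like cells. Free RNA was argued against as the whole cause, since the medians of all measured members relative to all genes were 0.24 (0.22 to 0.26) and 0.38 (0.36 to 0.41) after the rest of each library was subtracted at the share that supplies the other class's markers, 3.19 and 5.74% in AngII_VWR. Collection at another time of day may contribute in fibroblast-like cells, where the median log2 ratio of the clock genes Arntl, Clock and Npas2 lay 1.42 (1.33 to 1.53) above that of the other clock genes. In macrophage-like cells that difference was 0.16 (0.05 to 0.45). Both classes came from the same libraries, so the smaller difference there cannot exclude another collection time, which stays open. A stimulus shared by all cells of the library stays open, since the list had a median of 0.77 (0.41 to 0.85) over 11 members in the T-like class, and running was not separated from the preparation.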
